A study of Mus musculus with 6 samples.

How the data were processed

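Gene expression was measured by RNA sequencing in mouse CD8 T cells, the cytotoxic lineage of T cells, taken from spleen and lymph nodes. The cells had been activated with antibodies to CD3 and CD28, which stand in for the antigen receptor and costimulatory signals. Per the labels, activation lasted 3 days. Samples were grouped by the genotype label into wild type (WT, n = 3) and knockout of Ptpmt1 (KO, n = 3). The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

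The deposited table gives 1 FPKM value (fragments scaled to gene length and to library size) per gene and sample for 54532 genes, together with the deposited gene length in bases, a column of another kind that was used only to rebuild reads and to test for a length trend. Per the submitters' processing notes, Trim Galore, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 and the genome build mm10 were used, with no role or order stated. Per the labels' protocols, libraries were made with a stranded mRNA kit. The strand setting of the counting, the handling of reads with several matches and the annotation release are not given in the sources used here. Genes overlapping on opposite strands, and genes with near-identical copies, are therefore uncertain. In each deposited FPKM column, the value times gene length fell on whole multiples of 1 step, within a tolerance of 0.05, for at least 99.99% of values. Whole reads per gene were rebuilt from these steps. They summed to 14932604 to 16819913 per sample. The totals behind the FPKM were 0.780 to 1.096 times these sums, and lay 1.83% to 3.59% below totals set by median-of-ratios size factors.

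Gene identifiers were matched to GENCODE M21, which uses the mm10 build: 54409 identifiers matched and 123 did not. In the table, 27 gene names that read as dates were restored from the identifiers, and 203 rows shared a symbol. Coordinates are those of GENCODE M21, counted from 1.

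Values were analysed as log2(FPKM + 0.5) for the 12654 genes with a mean FPKM of at least 0.5 over the 6 samples. A fold change on this scale understates the change of low genes. Genotype was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 2-sided, genotype as the only term). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Of 40 gene lists fixed before the data were examined, 38 had at least 5 measured members and were tested with camera at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with the other genes, whereas fry, a rotation test, asks whether the genes of a list move 1 way on balance and compares them with no other genes. List members were also adjusted over the list alone. Genes within 1 Mb of Ptpmt1 were compared with all others by Fisher's exact test. For genes with no reads in 1 group, the fold is a lower bound against a floor of 3 reads over the group. For 1 to 3 reads, the ratio has a 95% exact Poisson interval. Both cover counting error only.

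Genes were named by a rule fixed before the data were examined. Ptpmt1 came first. Then came the 10 largest rises and 10 largest falls among called genes with a mean FPKM of at least 1 and groups that did not overlap, leaving out predicted genes, pseudogenes, receptor segments and ribosomal protein genes. Where fewer than 10 passed, those with the smallest unadjusted p filled the places and are said to have missed the threshold. From each list, up to 4 called members were named, or the 2 members of highest mean FPKM where none was called; these are given for the lists that passed and the effector list. Called genes outside the rule, and list members named because they passed when adjusted over the list alone, were chosen after their values were seen.

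The limma and camera steps were tested on simulated data for 12654 genes in 3 against 3 samples. Of 100 genes changed 2-fold, 39 were recovered. Of 100 changed 4-fold, 90 were recovered, and 11 unchanged genes were called. A list of 30 genes raised 1.5-fold was called, and 0 of 40 unchanged lists were. The simulated genes varied independently of each other. Genes of similar read count were given the same median variation, and no library was made to differ from the others as a whole. Recovery in the real data may therefore be lower. Alternatives covered the pseudocount, the filter on low values, the scaling, the variance model, sample weights, a replicate block, each sample left out in turn, limma-voom on rebuilt reads, and several gene subsets and thresholds. Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.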

Results

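The data comprised 6 RNA sequencing libraries of activated mouse CD8 T cells, 3 WT and 3 labelled as knockout of Ptpmt1 (KO), after 3 days of CD3 and CD28 stimulation. Ptpmt1 encodes a mitochondrial phosphatase of cardiolipin synthesis, cardiolipin being a lipid of the inner mitochondrial membrane. The comparison asks how expression differs between activated CD8 T cells with the WT and the KO label. Rebuilt reads totalled 16453314, 14932604 and 16374530 in WT replicates 1 to 3 and 16728995, 16819913 and 16462539 in KO replicates 1 to 3.

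Ptpmt1 (ENSMUSG00000063235, mm10 chromosome 2, 90908716 to 90918258, minus strand) was lower in each KO sample than in each WT sample. Its FPKM was 3.75, 3.84 and 4.13 in WT and 1.0004, 1.58 and 1.504 in KO. The group means were 3.90 ± 0.199 (SD, n = 3) and 1.36 ± 0.314 (SD, n = 3). The log2 fold change was -1.26 (SE 0.198, limma adjusted p = 0.0884), which missed the threshold over all genes. An exact 2-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples allow. Without KO replicate 3 the adjusted p was 0.0344. The labels used here do not say which exons were removed. Among the 25 measured genes within 1 Mb of Ptpmt1, 0 were called by limma and 5 had an unadjusted p under 0.05, a share of 20% against 21.8% of all other genes (Fisher's exact p = 1). Without KO replicate 3, 6 of these neighbours were called, 24% against 13.7% of the other genes (Fisher's exact p = 0.142).

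**Figure D1:**
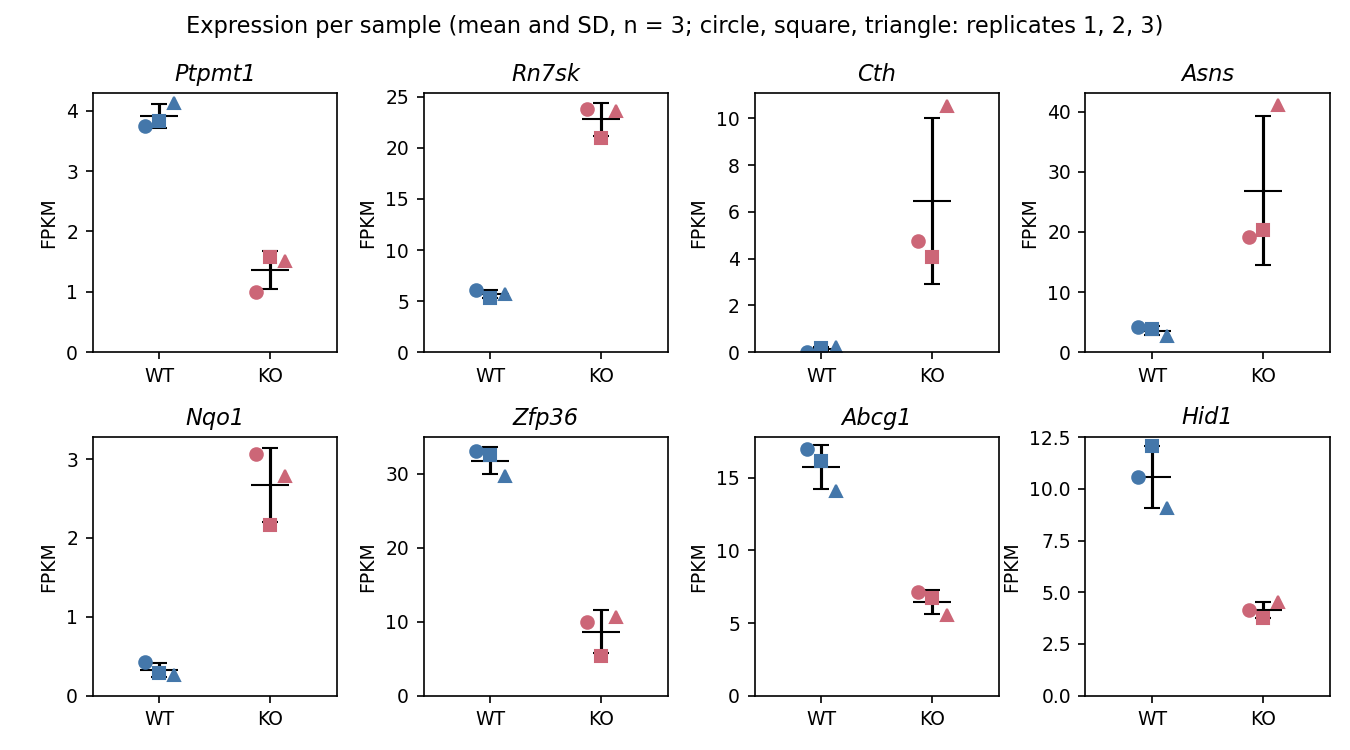
FPKM (linear axis) of Ptpmt1 and 7 other named genes in each sample, with the mean and SD of 3 WT (blue) and 3 KO (red) samples; circles, squares and triangles are replicates 1, 2 and 3. Ptpmt1 lay between 3.75 and 4.13 in WT and between 1.0004 and 1.58 in KO.

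Across the transcriptome, 5 genes were called, 3 higher and 2 lower in KO, and none was protein-coding. Rn7sk, the 7SK small nuclear RNA, rose from 5.69 ± 0.389 to 22.8 ± 1.59 FPKM (SD, n = 3 each; log2 fold change 1.91, SE 0.144, adjusted p = 0.0143). The libraries were made with an mRNA kit. Whether its reads track the amount of this noncoding RNA or its carryover in library preparation was not tested. The mitochondrial glycine tRNA mt-Tg rose from 0 reads in WT to 55, 97 and 24 reads in KO, at least 61.6-fold higher (adjusted p = 0.0216). The gene mt-Tg adjoins mt-Nd3, whose reads can be shared with nuclear copies. On the other side of mt-Nd3, mt-Tr had 1 read over the WT samples and 33 over the KO samples. Whether these tRNA counts reflect read assignment rather than expression was not tested. BC018473, a transcript annotated as antisense on chromosome 11, 116752167 to 116759373, fell from 666, 697 and 709 reads in WT to 0 in each KO sample, at least 657-fold lower (adjusted p = 0.000759). The predicted Gm42031 and the pseudogene Gm4864 lay outside the rule for names and were singled out after their values were seen. Gm42031, a predicted noncoding RNA on chromosome 8, fell from 1708 to 3 reads over the group, 542-fold higher in WT (95% counting interval 185 to 2630; adjusted p = 0.000759). Gm4864 rose from 0.303 ± 0.0696 to 9.29 ± 4.74 FPKM (SD, n = 3; adjusted p = 0.0378), and pseudogene reads can be shared with a parent gene.

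The other genes named by the rule missed the threshold, with adjusted p between 0.0614 and 0.0884. Among those higher in KO were enzymes of amino acid metabolism. Cth, which makes cysteine from cystathionine, had 0.137 ± 0.104 FPKM in WT and 6.46 ± 3.56 in KO (SD, n = 3; log2 fold change 3.35, SE 0.367). Asns, the asparagine synthetase, had 3.57 ± 0.785 and 26.8 ± 12.4 FPKM. Nqo1, a quinone reductase of the antioxidant response, had 0.328 ± 0.0928 and 2.67 ± 0.465 FPKM. Cox6a2, a subunit of cytochrome c oxidase typical of muscle, had 0.303 ± 0.118 and 28.2 ± 25.1 FPKM, with 17.5, 10.2 and 56.8 in KO replicates 1 to 3. Tnfsf11, the cytokine RANKL, had 2.72 ± 0.548 and 8.19 ± 0.605 FPKM. Dnph1 had 6.63 ± 0.934 and 19.2 ± 1.73 FPKM, and Akr1c12 had 1.49 ± 0.231 and 5.58 ± 0.988. The mitochondrial complex I gene mt-Nd3 had 6.30 ± 1.22 FPKM in WT and 135.6 ± 80.0 in KO, and its reads can be shared with nuclear copies.

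Among the genes lower in KO, Zfp36, an mRNA-destabilising protein, had 31.8 ± 1.80 FPKM in WT and 8.66 ± 2.91 in KO (SD, n = 3; log2 fold change -1.87, SE 0.264). Abcg1, a cholesterol exporter, had 15.7 ± 1.48 and 6.45 ± 0.833 FPKM. The sialyltransferase gene St6galnac2 (ENSMUSG00000057286) had 632 reads over the WT samples and 8 over the KO samples. Hid1 had 10.6 ± 1.496 and 4.13 ± 0.387 FPKM, Scml4 had 15.6 ± 1.76 and 6.79 ± 0.343, and Ganc had 5.88 ± 0.447 and 2.52 ± 0.0762. Izumo4, Tecpr1 and Ndrg3 completed the set, with log2 fold changes of -1.08, -1.24 and -1.14.

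At an unadjusted p under 0.05, limma gave 2756 genes, 1459 higher and 1297 lower in KO, and 307 genes had an adjusted p under 0.1. The groups did not overlap for 27.8% of genes, where chance gives 10% on average over all splits of the samples. Where genes vary together, a single split can lie far from that average. Other splits into groups of 3 gave 83 to 1587 genes at an unadjusted p under 0.05 in limma. The count of 5 depended on KO replicate 3: without it 1733 genes were called, and without any other single sample 2 to 5. With each sample rescaled to the same total, the median log2 fold change of all genes was -0.22, and 22.9% of genes with an unadjusted p under 0.05 were higher in KO, against 52.9% as deposited.

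The libraries of the KO group differed from each other. KO replicate 2 had 7.53% of reads from mitochondrial genes and 19.1% from ribosomal protein genes. KO replicate 3 had 2.38% and 11.0%, and the other 4 libraries had 3.38% to 4.76% and 12.9% to 15.3%. KO replicate 3 also had no reads of Xist, which is expressed from the inactive X chromosome of females, and 1837 reads of the Y-linked Ddx3y. The other 5 libraries had at least 3513 reads of Xist and 0 of Ddx3y.

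**Figure D2:**
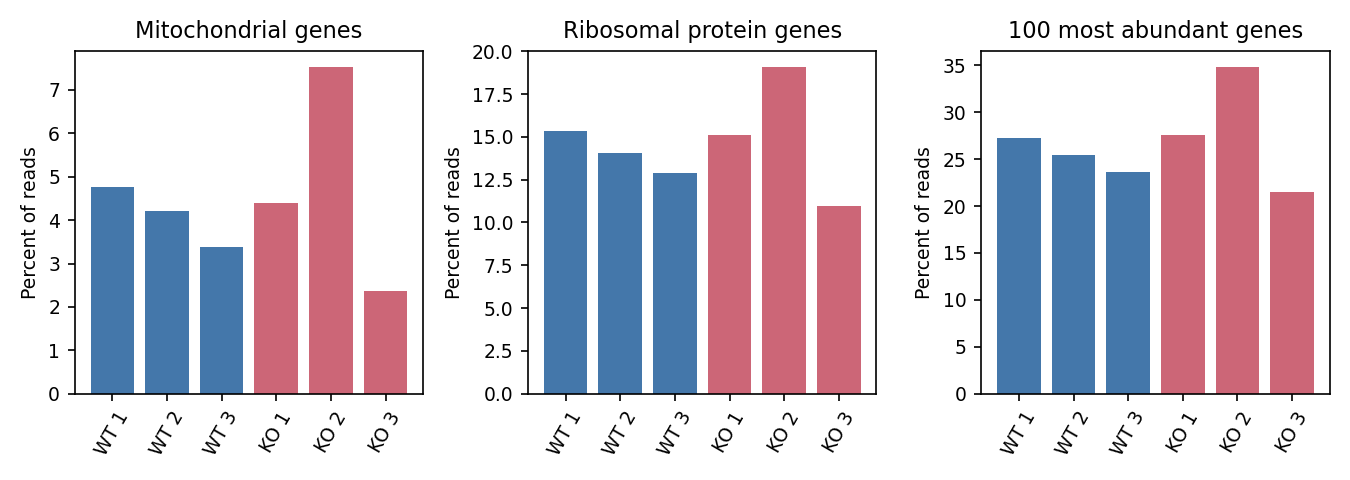
Percent of reads in each library from mitochondrial genes, ribosomal protein genes and the 100 most abundant genes of that library; bars are single WT (blue) and KO (red) samples, so no error bars are drawn. KO replicate 2 has the highest share in each panel (7.53%, 19.1% and 34.8%) and KO replicate 3 the lowest (2.38%, 11.0% and 21.5%).

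Of the 38 gene lists tested, 12 passed camera at the preset correlation, 10 higher and 2 lower in KO, and 0 passed with an estimated correlation. Over all genes, 0 members of these 12 lists were called. Genes of ribosome biogenesis and MYC targets were higher in KO for 30 of 30 measured members (median log2 fold change 0.83, adjusted p = 3.52e-11; adjusted p = 0.503 with an estimated correlation). Of these, 18 passed adjusted over the list alone. WT replicate 3 had a mean list score of 0.44, against -0.17 and -0.27 in WT replicates 1 and 2 and 0.76 to 0.97 in KO. The list members of highest FPKM were the nucleolar protein Npm1, at 1016 ± 158 in WT and 2187 ± 1198 in KO (SD, n = 3; adjusted p over the list alone 0.101), and the translation factor Eif4a1, at 149.2 ± 20.2 and 266.4 ± 41.0 (0.0168).

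Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, were higher in KO for 30 of 33 measured members (median 1.002, adjusted p = 6.81e-10; adjusted p = 0.674 with an estimated correlation). Adjusted over the list alone, 17 passed. Phgdh, the first enzyme of serine synthesis, had 116.4 ± 22.8 FPKM in WT and 251.9 ± 15.2 in KO (SD, n = 3), and Atf4 itself had 59.4 ± 6.15 and 121.7 ± 31.8. The mean score of the list in KO replicate 3 was 1.81, against 0.83 and 0.58 in KO replicates 1 and 2. Amino acid transport, glutaminolysis and one-carbon metabolism were higher in 28 of 30 members (median 0.77, adjusted p = 1.25e-08; adjusted p = 0.503 with an estimated correlation). Adjusted over the list alone, 11 passed, among them Psat1, at 34.6 ± 3.68 and 80.1 ± 12.3 FPKM, chosen after its value was seen. Paics, of purine synthesis and of high FPKM in this list, had 130.7 ± 21.0 and 177.2 ± 50.8. WT replicate 3 had a mean score of 0.31 for the amino acid list, against 0.53 to 0.92 in KO. Phgdh, Psat1, Psph, Shmt2, Mthfd2, Slc7a5 and Slc3a2 stand in both lists, so the results of these lists are partly the same evidence.

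Of the lists of mitochondrial proteins, 4 were higher. The mitochondrially encoded chain did not pass (9 of 13 members higher, median 0.17, adjusted p = 0.520), and its median was -0.50 without KO replicate 2. Without KO replicate 3 it passed (median 0.78, adjusted p = 0.0123). Fusion, fission and mitophagy did not pass either (9 of 18 higher, median 0.10, adjusted p = 0.557). The median of that list was -0.01 without KO replicate 2 and 0.22 without KO replicate 3. With each sample rescaled to the same total it was -0.16, where that of all genes was -0.22. The chaperones and proteases were higher in 13 of 14 members (median 0.61, adjusted p = 8.13e-05; adjusted p = 0.503 with an estimated correlation), with 2 passing when adjusted over the list alone. The chaperonin Hspd1 had 140.7 ± 40.2 FPKM in WT and 313.9 ± 23.7 in KO (SD, n = 3), and its partner Hspe1 had 197.2 ± 19.3 and 409.8 ± 200.1. The biogenesis list was higher in 18 of 21 members (median 0.39, adjusted p = 0.00190; adjusted p = 0.503 with an estimated correlation), and 1 passed when adjusted over the list alone, the import channel gene Timm23, at 33.0 ± 5.47 and 74.1 ± 4.04 FPKM. Tomm20 had 47.8 ± 4.27 and 67.3 ± 13.8 FPKM. Nuclear genes of the respiratory chain and ATP synthase were higher in 55 of 61 (median 0.43, adjusted p = 3.59e-05; adjusted p = 0.830 with an estimated correlation). In limma 0 passed adjusted over the list alone, and 10 had an unadjusted p under 0.05, all higher in KO. Of all 12654 genes, 2756 had such a p, 1459 of them higher. Cox8a had 603.4 ± 55.8 FPKM in WT and 860.4 ± 399.5 in KO (SD, n = 3), and Uqcr10 had 237.1 ± 45.9 and 521.4 ± 340.2. Their mean score was 0.58 and 0.92 in KO replicates 1 and 2 and -0.15 in KO replicate 3, libraries in which mitochondrial genes took 4.40%, 7.53% and 2.38% of reads. The median of the list was 0.21 without KO replicate 2 (adjusted p = 0.0193) and 0.74 without KO replicate 3. Histone genes without poly(A) tails, a list fixed as a check of RNA quality, ran alongside, with scores of 0.67, 0.85 and -0.51 in KO replicates 1 to 3. That list did not pass (median 0.34, adjusted p = 0.266), but did without KO replicate 3 (0.00316) and without WT replicate 3 (0.0246). Pyruvate entry and the TCA cycle were higher in 24 of 28 (median 0.35, adjusted p = 0.00723; adjusted p = 0.674 with an estimated correlation). The mean score of the list was 0.38, 0.42 and 0.097 in KO replicates 1 to 3, the last below the 0.108 of WT replicate 3. In limma 0 passed adjusted over the list alone, and 6 were higher and 1 lower at an unadjusted p under 0.05. Mdh1, the cytosolic malate dehydrogenase, had 158.4 ± 21.5 and 259.8 ± 179.6 FPKM, and its log2 fold change of 0.44 became -0.10 without KO replicate 2. Sdhd had 172.4 ± 18.2 and 277.7 ± 139.7 FPKM. With each sample rescaled to the same total, the TCA list no longer passed (median 0.09, adjusted p = 0.0527). Without KO replicate 2 the medians of the TCA and biogenesis lists were 0.23 and 0.26, and both passed.

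DNA replication and G1/S genes were higher in 43 of 46 members (median 0.36, adjusted p = 2.34e-05; adjusted p = 0.695 with an estimated correlation). In limma 0 passed adjusted over the list alone, and 10 had an unadjusted p under 0.05, all higher in KO. Of all 12654 genes, 2756 had such a p, 1459 of them higher. Pcna had 294.3 ± 33.4 FPKM in WT and 499.8 ± 233.7 in KO (SD, n = 3), and Mcm5 had 101.1 ± 13.7 and 123.2 ± 9.96. The antioxidant and pentose phosphate list was higher in 25 of 30 (median 0.35, adjusted p = 0.000837; adjusted p = 0.503 with an estimated correlation), and Nqo1 was the 1 member that passed adjusted over the list alone. Of highest FPKM were Txn1, at 403.5 ± 47.3 and 719.3 ± 274.1, and Fth1, at 321.7 ± 20.7 and 358.4 ± 28.9. After the same rescaling the medians were 0.09 for DNA replication, 0.08 for antioxidant, 0.16 for respiratory chain and 0.15 for biogenesis genes, against -0.22 for all genes. They were 0.35 for the chaperones and proteases, 0.50 for the amino acid list and -0.63 for the CD8 T cell identity list, and all of these lists still passed. Cytokines and chemokines were higher in 18 of 23 (median 0.81, adjusted p = 0.00723; adjusted p = 0.773 with an estimated correlation), with 3 passing adjusted over the list alone. The members of highest FPKM went the other way, Ltb at 350.2 ± 11.7 and 284.1 ± 82.6 and Ccl5 at 63.2 ± 18.4 and 42.8 ± 17.8. The mean score of the list was 0.54 in WT replicate 3, above the 0.15 and 0.32 of KO replicates 1 and 2, and 1.24 in KO replicate 3. Without KO replicate 3 the cytokine list had a median of 0.26 and an adjusted p of 0.348. KO replicate 3 and WT replicate 3 also scored highest for markers of gamma-delta T cells (2.29 and 0.72), neutrophils and mast cells (1.61 and 0.67), and macrophages, monocytes and dendritic cells (0.87 and 0.39).

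Naive and memory-associated genes were lower in KO for 28 of 32 members (median -0.79, adjusted p = 6.55e-09; adjusted p = 0.503 with an estimated correlation). Adjusted over the list alone, 16 passed. WT replicate 3 had a mean list score of -0.34, against 0.16 and 0.18 in WT replicates 1 and 2 and -0.73 to -0.60 in KO. Tcf7, a transcription factor of naive and memory T cells, had 488.6 ± 41.8 FPKM in WT and 237.2 ± 40.1 in KO (SD, n = 3), and Dapl1 had 281.2 ± 104.4 and 221.7 ± 231.7. The CD8 T cell identity list was lower in 14 of 16 (median -0.36, adjusted p = 0.00391; adjusted p = 0.503 with an estimated correlation). In limma 0 passed adjusted over the list alone, and 5 had an unadjusted p under 0.05. The receptor constant genes Trbc1 and Trbc2 had log2 fold changes of 0.04 (SE 0.548) and 0.05 (SE 0.540), whose sign depended on which sample was left out. The median of this list was -0.23 and its adjusted p 0.0775 without KO replicate 3. Its score was lowest in that library, at -0.62 against -0.23 and -0.10 in KO replicates 1 and 2. That library scored highest for the other-cell markers above and for CD4 and regulatory T cell markers (0.91). The latter list holds Il2ra, which also stands in the effector and activation lists. KO replicate 3 did not score highest for natural killer (-0.36, KO replicate 2 0.58), B cell (0.09, WT replicate 3 0.23) or erythroid and platelet markers (0.39, WT replicate 3 0.86).

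**Figure D3:**
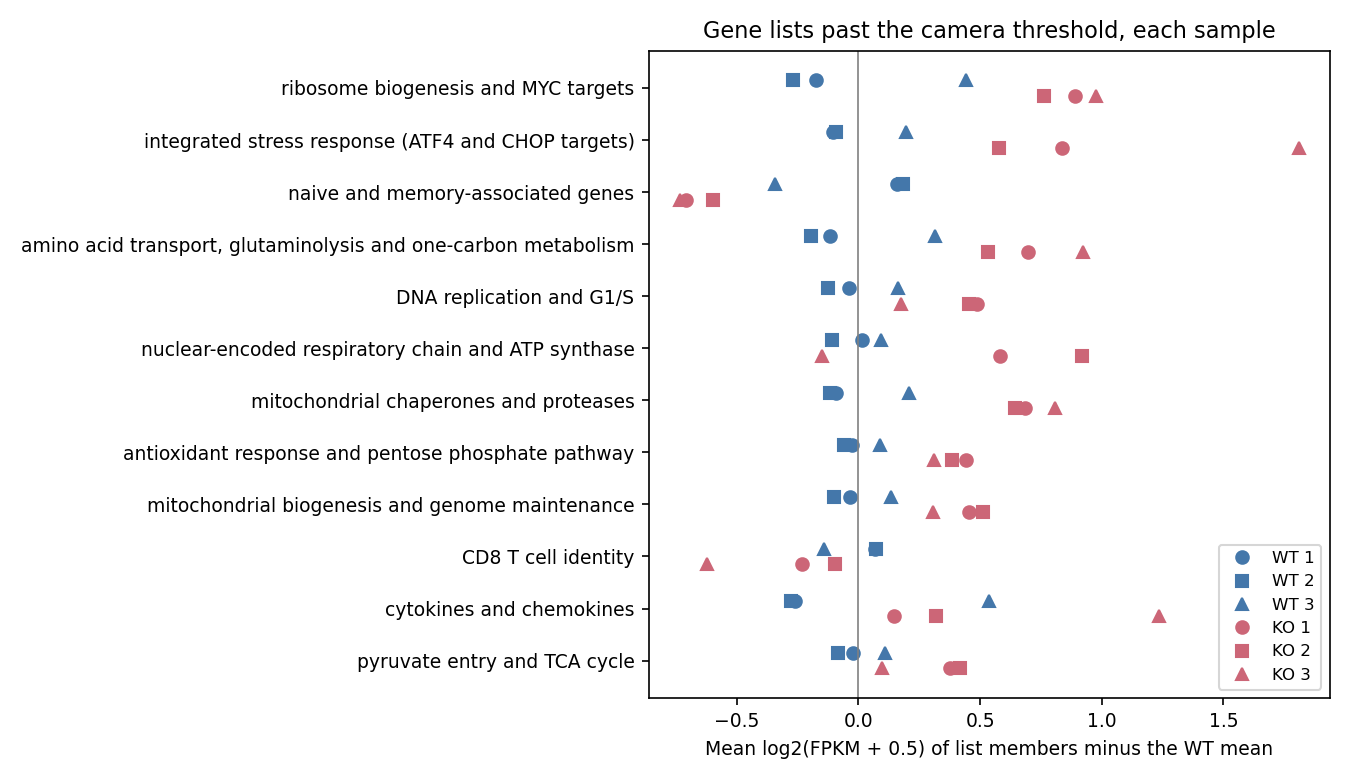
Mean of log2(FPKM + 0.5) over the measured members of each of the 12 lists that passed camera, minus the WT mean (horizontal axis, log2 units), with 1 point per sample for WT (blue) and KO (red). Naive and memory-associated genes lie between -0.73 and -0.60 in KO, and the respiratory chain list lies at -0.15 in KO replicate 3 against 0.58 and 0.92 in the other KO samples.

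Cytotoxic effector genes missed the threshold as a list (median 0.42, adjusted p = 0.0667), with 22 of 32 members higher in KO and 4 passing adjusted over the list alone. It passed in 4 of 12 camera alternatives: with the replicate block (adjusted p = 0.0115), without WT replicate 3 (0.0189), without KO replicate 1 (0.00562) and rescaled to equal totals (0.0495). Its median ranged from 0.17 to 0.52. The granzyme Gzmb had 254.0 ± 83.1 FPKM in WT and 694.1 ± 67.8 in KO (SD, n = 3), while Nkg7 had 159.5 ± 6.002 and 147.2 ± 14.1. The cardiolipin list, which leaves out Ptpmt1, had a median of 0.24 and an adjusted p of 0.148. Glycolysis (median 0.02, adjusted p = 0.869), G2/M and mitosis (median 0.02, adjusted p = 0.851), hypoxia-inducible genes (median 0.19, adjusted p = 0.935) and exhaustion-associated genes (median 0.13, adjusted p = 0.869) did not pass. A median near 0 can hide members that moved both ways. At an unadjusted p under 0.05 in limma, 5 of 23 glycolysis genes were higher and 4 lower. The counts were 3 and 4 of 24 for hypoxia, 1 and 2 of 50 for G2/M, and 1 and 2 of 25 for exhaustion. For G2/M, hypoxia and exhaustion the camera direction was down although the median was above 0. The medians of these 4 lists changed sign between alternatives. Rescaling to equal totals, which took the median of all genes to -0.22, gave the lowest values. These were -0.25 for glycolysis and G2/M, -0.08 for hypoxia and -0.14 for exhaustion. In the other alternatives the medians ranged from -0.09 to 0.09 for glycolysis and -0.08 to 0.15 for G2/M. For hypoxia they ranged from -0.03 to 0.24 and for exhaustion from -0.03 to 0.31. The cardiolipin median was below 0 only after rescaling (-0.02) and ranged from 0.04 to 0.28 otherwise. None of the other lists passed. Nearest was the endoplasmic reticulum unfolded protein response (median 0.31, adjusted p = 0.0605), which passed in 4 of 12 camera alternatives. Its median was 0.11 without KO replicate 3 (adjusted p = 0.495) and 0.05 after rescaling to equal totals. Among markers of other cell types, those of B cells came nearest (median -0.45, adjusted p = 0.0809), passing in 4 of 12 alternatives. The cholesterol, interferon, activation, gamma-delta T cell, and neutrophil and mast cell lists each passed in 1 of 12.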

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

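The threshold of an adjusted p under 0.1, the gene-length correction, limma-voom scaled to the read totals, list tests after length correction or rescaling to equal totals, and the recounts of neighbours were chosen after seeing the data. Against 5 genes called (3 higher, 2 lower), pseudocount 1 gave 3 (1 higher), no filter 3 (1 higher), a mean FPKM of at least 5 gave 3 (1 lower), quantile normalization 8 (6 higher), no trend 14 (9 higher, 5 lower), limma-voom 1 (0 higher, 1 lower), and limma-voom scaled to the read totals 3 (0 higher). Protein-coding genes alone gave 10. These share 0 with the 5, which was fixed in advance because none of the 5 is protein-coding. Leaving out mitochondrial and the 100 most abundant genes and rescaling the rest to equal totals, 2 changes at once, gave 2. An adjusted p under 0.01 gave 2, and under 0.1 gave 307 (161 higher, 146 lower). Leaving out single samples gave 2 to 1733 genes (0 to 1027 higher, 2 to 706 lower), the top of each range without KO replicate 3. The 1733 include all 5, and the cause was not tested. Array weights gave 7200 genes (3834 higher, 3366 lower), 15 neighbours of Ptpmt1 and a Ptpmt1 log2 fold change of -1.52 (adjusted p = 0.000199; range over the alternatives 0.000199 to 0.4265). This fit did not converge and put a weight of 36.4 on KO replicate 1, against 0.230 and 0.154 on KO replicates 2 and 3. The KO mean was then nearly that of 1 library, and the count is not a usable number of changes.

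Ptpmt1 was lower in KO under every alternative in which it was tested. A mean FPKM of at least 5 removed it. The limit to protein-coding genes removed it too, because the annotation used lists Ptpmt1 as a processed transcript. Leaving out single samples moved its log2 fold change from -1.34 to -1.11, with an adjusted p of 0.0344 and a log2 fold change of -1.32 without KO replicate 3, and called 0 to 6 neighbours. The replicate block gave 12 genes (7 higher, 5 lower). Same-numbered samples deviated together with correlations of 0.132, 0.0665 and 0.331, not all over 0.1. WT replicates 1, 2 and 3 correlated best with KO replicates 2, 1 and 3. So few samples cannot decide whether equal numbers mark a shared day or litter. The 12 lists called became 0 with an estimated correlation. By fry, which asks a different question, 2 passed (antioxidant and cardiolipin, the latter not among the 12). Named genes gave 525 values on the same side of the threshold, 44 newly past it, 15 no longer past it and 6 of opposite sign, all 6 far from the threshold. These were Trbc2 (-0.08 without WT replicate 3, -0.02 without KO replicate 1, -0.45 without KO replicate 2), Trbc1 (-0.08 without WT replicate 3, -0.50 without KO replicate 2) and Mdh1 (-0.10 without KO replicate 2). Without KO replicate 3 they kept their sign, at 0.63, 0.63 and 1.07, the highest of their ranges. The cause was not tested.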

Other observations

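All tests of explanations below were chosen after the results were seen. Several genes of heat shock and of the early response to sample handling, a list fixed as a check of RNA quality, went both ways. Zfp36, Dusp1 and Fos were lower in KO, with Dusp1 at 11.6 ± 2.56 FPKM in WT and 4.01 ± 0.556 in KO (SD, n = 3), and the heat shock genes Hsp90aa1 and Hsph1 were higher, Hsp90aa1 at 232.6 ± 38.0 and 701.2 ± 319.3. Each passed adjusted over the list alone and none over all genes. The list as a whole did not pass camera (adjusted p = 0.352). Lag3, an inhibitory receptor, had 22.2 ± 0.825 and 10.3 ± 2.75 FPKM, and the lactate transporter Slc16a1 had 23.1 ± 1.66 and 47.9 ± 4.89. These were named after their values were seen.

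With 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split gave 5 genes and the highest other split 1, and 1 of the 10 splits reached the real count. Counted by direction, the real split gave 3 higher and 2 lower, and the highest other split 0 and 1. In each direction 1 split of 10 reached the real count. The other splits mix the genotypes and have no KO side. Which of their genes count as higher is therefore arbitrary, and the direction of their counts has no meaning.

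The 12 gene lists that moved together form the first pattern. With the gene-length trend removed, 12 of the 12 still passed, which argues against gene length as the whole cause. Without KO replicate 3, the male library, 10 passed in the same direction, which argues against that library as the only source, though the cytokine and CD8 identity lists were lost. The real split called 12 lists, but 4 other splits called as many or more, up to 22. Thus 5 of 10 splits reached the real count. Variation shared between libraries whatever their genotype may produce such calls at a preset correlation. Each other split, however, sets 2 samples of 1 genotype and 1 of the other against the reverse. It therefore still holds part of the genotype contrast, and these counts cannot separate genotype from shared variation. A p as small as the real one came in 5 of 10 splits for cytokines and 4 for the respiratory chain. It came in 3 for the stress response and 2 for DNA replication and the TCA cycle. For the other 7 lists it came in the real split alone, but these lists also passed the threshold in other splits. With the real split counted, the amino acid list passed in 7 of 10, ribosome biogenesis in 6, and chaperones and CD8 identity in 5 each. Naive and memory-associated genes passed in 4, and the antioxidant and mitochondrial biogenesis lists in 3 each. The rank of the real split alone therefore does not tie these lists to genotype.

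The second pattern is mt-Nd3, on the mitochondrial genome at 9459 to 9806, next to mt-Tg and mt-Tr. The other 12 mitochondrial coding genes had a median log2 fold change of 0.14 against 4.12 for mt-Nd3, which argues against a rise of the whole mitochondrial transcriptome. The nuclear copy Gm28438 went the other way, from 561, 581 and 644 reads in WT to 221, 90 and 33 in KO. Their scaled sum was 1.42 times higher in KO, with overlapping groups, against 21.5 times for mt-Nd3 alone, a value consistent with reads assigned to different copies in the 2 groups. The overlap rests on KO replicate 3, whose scaled sum of 201.1 lay below the WT range of 362.8 to 397.2, while KO replicates 1 and 2 had 635.3 and 806.9; a sequence difference of the mitochondrial genome between the groups stays open, as reads were not used here.

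The third pattern is a block on chromosome 11. St6galnac1 (116765025 to 116775507) had 178 reads over the WT samples and 0 in KO, at least 56.5-fold lower, next to BC018473, Gm11735 (77 and 1 reads) and St6galnac2 (632 and 8 reads). Of these 4 genes, 3 had at least 100 WT reads, which argues against low depth. Among the 74 other measured genes within 2 Mb, 24.3% had an unadjusted p under 0.05 against 21.7% elsewhere (Fisher's exact p = 0.573), so the share did not differ detectably, although 12 of the 18 were lower in KO and Hid1 is among them, and a wider linked interval is not excluded. A deletion, a strain difference at this place or an effect of the knockout cannot be told apart, because any of these follows the genotype groups.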
